A study of Mus musculus with 24 samples.

How the data were processed

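RNA from 24 samples of the mouse leukaemia line DA1-3B, in 6 groups of 4, was hybridised in one colour (Cy3) to Agilent arrays, 4 arrays to a slide on 6 slides, with more than 1 group on each slide. Per the file headers, the authors read the scans with Agilent Feature Extraction 10.7.3.1 and the deposited values are processed signal intensity: background-subtracted, spatially detrended, on a linear scale and not normalized between arrays. The deposited series table holds the same intensity values (largest difference 0). The deposited files also hold raw spot and background intensity, and per-spot quality marks of other kinds (well above background, saturated, non-uniform). The 44397 spots include 43020 that are not controls, with 39429 distinct probes and 27499 distinct gene names; names came from RefSeq accessions where these matched and otherwise from the array files. No spot was saturated, and 185 to 312 spots per array were marked as uneven and left out. The median coefficient of variation of repeated spots on 1 array was 3.57% to 5.64%.

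Log2 processed signal minus each array's own 75th percentile was the measure. Probes had to be well above background on all 4 arrays of at least 1 group, which left 19523 probes, and the probe with the highest mean stood for each of 15054 genes. With R 4.3.3 and limma 3.58.1, with the packages data.table (version 1.17.8) and statmod (version 1.5.0), a linear model with 1 mean per group was fitted to all 24 arrays (18 residual degrees of freedom, 3.06 prior degrees of freedom). It gave 10 comparisons: each construct against VOID, each other construct against WT, and the additivity of the fragments (both fragments minus VOID, less the separate changes of each fragment). A moderated F test asked for any difference among the 6 groups. Calls have a Benjamini-Hochberg adjusted p under 0.05 within a comparison, 2-sided. Errors are limma standard errors on the log2 scale. Where the dimmer group was above background on 0 of 4 arrays, the fold is a lower bound, taken against the background level and written as at least N-fold.

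Gene lists, 32 in number, were tested in all 10 comparisons (320 tests, adjusted together) with limma's camera at a preset correlation of 0.01, with the estimated correlation and fry beside it. They cover NF-kB targets and pathway, apoptosis, BCR-ABL and STAT5 response, stress, immune signalling, cell cycle, metabolism, and markers of blood and other cell types. The named genes followed a rule: Rela, Abl1 and Bcr; the 6 largest rises and 6 largest falls against VOID, and the 4 and 4 largest in the other comparisons, among called genes whose groups' arrays did not overlap (no such demand for additivity), with the brighter group above background on all 4 arrays; and up to 4 members of each list that passed. The groups, measure, filter, tests, lists, naming rule and most alternatives were set before the data were examined.

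The alternatives were normexp background correction (offset 50), quantile normalization, no filter on dim probes, only probes well above background on all 24 arrays, the authors' series table, slide as a fixed or random block, only the arrays compared, the mean of a gene's probes, every probe on its own, array weights, a trended and robust prior, VOID arrays split between constructs, and each array left out in turn. Added after the data were examined were the 75th percentile over detected probes, the 4 sets of consecutive sample numbers as a fixed block, array brightness as a covariate, and the 3 arrays that resembled another group left out, for the lists also with the estimated correlation. For that resemblance, each array was correlated with the 6 group means of the other 3 sets, over the 200 genes with the smallest F test p in those sets, after the mean of the groups was removed. The labels call neither slides nor sets batches; slides were read from the file headers. Replicate numbers follow the order of the samples. The fit was tested on simulated data, where 11 of 15054 genes were called falsely in WT against VOID beside 200 changed ones, and 0 of 320 list tests. On the real arrays the list test at the preset correlation was far less strict, with a median of 67 list calls over random regroupings. Group labels were also exchanged among the arrays compared, in all 35 splits of 8 arrays, or in 100 random regroupings, and for 2 comparisons also within the sets of sample numbers.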

Results

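Gene expression was measured in DA1-3B cells, a mouse leukaemia line that carries the Bcr-Abl oncogene, after transfection with plasmids for p65/RelA, a subunit of the transcription factor NF-kB. The 6 groups of 4 arrays were the empty plasmid (VOID), full-length p65 (WT), the non-cleavable mutant D361E, the N-terminal fragment p1-361, the C-terminal fragment p363-549, and both fragments together. One-colour arrays held 44397 spots, of which 43020 were not controls. Between 49.4% and 55.5% of these spots were well above background on each array, and the 75th percentile of the signal ran from 635.8 to 1214. The number of arrays limits the precision. The labels do not say whether the 4 samples of a group came from separate cultures, so the p-values measure the spread between these samples. The treatment protocol starts the C-terminal fragment 1 residue earlier than the sample names do.

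In 21 of the 24 arrays, the pattern of expression was closest to the array's own group. The comparison used the mean of each group over the arrays of the other 3 sets of consecutive sample numbers, across 200 genes. These correlations are across genes, and genes are not independent replicates. The 3 exceptions were the fragment arrays numbered 4. Replicate 4 of p363-549 had a Pearson r of 0.97 with the both-fragment mean and -0.55 with its own group. For p1-361 replicate 4, r was 0.78 with p363-549 and 0.14 with its own group. The replicate 4 array of both fragments had an r of 0.71 with p1-361 and -0.09 with its own group. The other 21 arrays had an r of 0.52 to 0.95 with their own group. All results below keep the groups as labelled, so each fragment group holds 1 array that resembled another fragment group. Each total of genes that passed the test is also given without these 3 arrays. That choice was made after the data were examined, and because the arrays were picked by their values, the spread within groups is lower by choice.

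**Figure D1:**
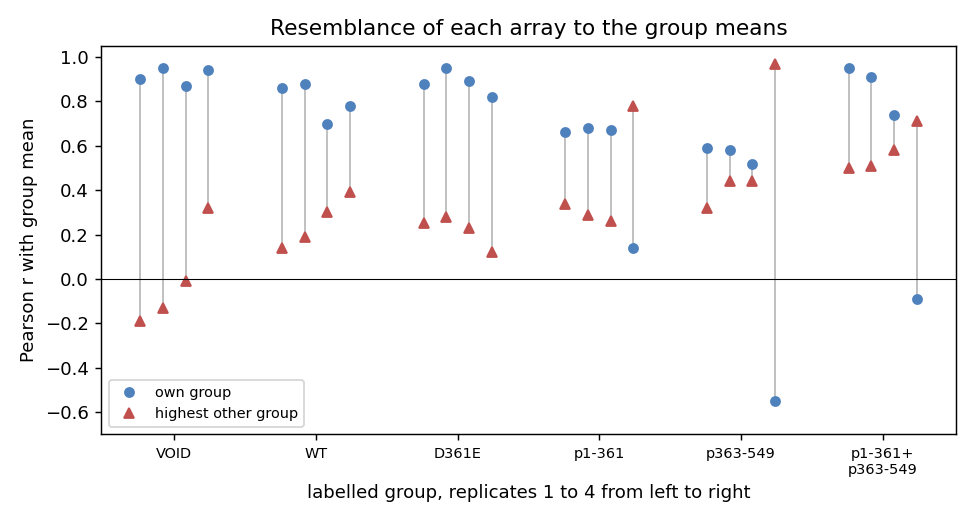
Pearson r of each array with its own group mean (circles) and with the highest other group mean (triangles), across 200 genes chosen without the array's own set; arrays are ordered by labelled group and replicate. In 21 of the 24 arrays the circle is above the triangle, and the 3 fragment arrays numbered 4 are the exceptions.

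Among 15054 genes tested, 424 differed somewhere among the 6 groups in limma's moderated F test. The number was 1480 without the 3 arrays. Without a single array it was 252 (both fragments replicate 1), 265 (both fragments replicate 2), 795 (p363-549 replicate 4) and 792 (both fragments replicate 4), and it was 136 after normexp background correction. Over all 15054 genes the 4 arrays of 1 group lay apart from the 4 of the other for 718 (WT), 716 (D361E), 714 (p1-361), 497 (p363-549) and 1520 (both fragments) against VOID, where chance separates 430 genes (2.86%). Against WT the numbers were 543 (D361E), 420 (p1-361, no more than by chance), 563 (p363-549) and 1124 (both fragments). Raw p under 0.05 was found for 462 genes in D361E and 454 in p1-361 against WT, where chance gives 753. These 2 comparisons so showed no excess of small p-values over all genes in this fit. Its spread is shared by all 24 arrays, the 3 exceptions included, and the totals of called genes in both comparisons rose without those 3.

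**Figure D2:**
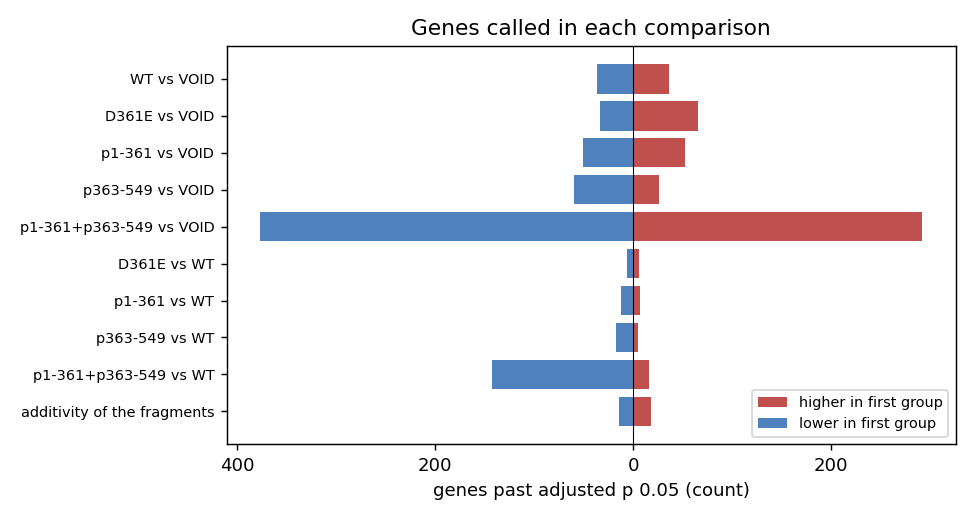
Number of genes higher (right) and lower (left) in the first group of each comparison at a limma adjusted p under 0.05, with all 24 arrays. Both fragments against VOID gave 292 higher and 377 lower genes, and full-length p65 against VOID gave 36 higher and 37 lower.

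Rela itself was read by a single probe on chromosome 19, bases 5648070 to 5648129 of build mm9, which begins at base 2648 of its transcript. Whether the probe lies in the transfected coding part was not settled, so it does not check the labels. Rela was higher than in VOID by 0.40 ± 0.10 (log2, SE, n = 4 arrays per group) in WT, which missed the test at an adjusted p of 0.0794, and by 0.36 in D361E (adjusted p = 0.127). It rose by 0.43 in p1-361 (adjusted p = 0.041), by 0.49 in p363-549 (adjusted p = 0.0161) and by 0.47 with both fragments (adjusted p = 0.00624). The 2 single fragments share no residues, so 1 probe cannot lie whole in the coding part of both. The transfected coding part therefore cannot account for the rise in both of them. The WT difference was 0.41, 0.44, 0.39 and 0.35 within the 4 sets of sample numbers, and it passed with the sets as a fixed block (adjusted p = 0.0137), after quantile normalization (0.0374), with the 75th percentile over detected probes (0.0407) and without the 3 arrays (0.0469). The p1-361 call held in 10 of 24 settings and ended without any 1 of the 8 arrays, the p363-549 call held in 17 of 24, and that of both fragments in 22 of 24. Normexp correction and fits of only the arrays compared ended all 3 calls, and slide as a fixed block and no filter on dim probes ended the first 2. Abl1 and Bcr, the partners of the fusion oncogene, did not pass the test in any comparison.

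Full-length p65 against the empty plasmid asked which genes p65 regulates. Among known NF-kB target genes, Tnfaip3, an enzyme that restrains NF-kB signalling, rose by 2.34 ± 0.27 (log2, SE, n = 4 arrays per group; adjusted p = 2.4e-05), and Nfkbie, an inhibitor that binds NF-kB, rose by 1.29 ± 0.20. The cytokine genes Lta and Ltb, of the tumour necrosis factor family, rose by 2.76 ± 0.47 and 1.45 ± 0.24, with Lta above background on 1 of 4 VOID arrays. Of 41 measured NF-kB targets, 7 rose, 0 fell and 34 did not pass; adjusted over the list alone, 12 rose and 1 fell. Their mean log2 change was 0.44 (camera adjusted p = 8.61e-13, adjusted p = 0.0499 with an estimated correlation). The kinase genes Map3k19 and Prkd3 rose at least 2.33-fold and at least 1.82-fold, from a signal above background on 0 of 4 VOID arrays, and Podnl1, with 2 of 4 VOID arrays above background, rose 13.9-fold.

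All 7 measured globin genes fell in WT, by log2 changes from -2.40 (Hba-a2) to -6.20 (Hbb-bs). F13a1, a subunit of a clotting factor, fell by 6.21 ± 1.04, with its other probe at -4.33. Vwf, another clotting protein, fell by 2.25 ± 0.42, with a signal above background on 1 of 4 WT arrays. Of the 18 measured erythroid and megakaryocyte markers, 0 rose, 4 fell and 14 did not pass; adjusted over the list alone, 2 rose and 4 fell. As a list these markers missed the test (adjusted p = 0.143), with a mean of -0.55 and a median of -0.04. Monocyte and macrophage markers had 2 of 15 higher, the lysozyme genes Lyz1 and Lyz2 (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00232, adjusted p = 0.291 with an estimated correlation). Interferon-stimulated genes had 1 of 33 higher, Gbp2, a guanylate-binding protein (2 adjusted over the list alone; adjusted p = 1.22e-05, adjusted p = 0.149 with an estimated correlation). In total 36 genes rose and 37 fell in limma, and 56 passed with slide as a fixed block. With the sets of sample numbers as a fixed block 221 passed, and 116 in a fit of these 8 arrays only. Within the 2 slides that held both groups the mean change of the NF-kB targets was 0.39 and 0.59. The total was 191 without the 3 arrays, all 73 included, 45 without VOID replicate 2, 45 without WT replicate 2 and 27 after normexp correction, which ended the call of 8 of the 20 named genes, Map3k19, Prkd3, Gbp2, Lyz1, Lyz2 and Vwf among them. Lyz1 and Lyz2 also lost their call with slide as a fixed block and without any 1 of VOID replicates 1 and 2 and WT replicates 2, 3 and 4, and Lyz2 without VOID replicate 4.

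The non-cleavable mutant D361E against VOID asked which genes p65 regulates when it cannot be cleaved at that site. Tnfaip3 rose by 1.79 ± 0.27 (log2, SE, n = 4 arrays per group; adjusted p = 0.000983), Ltb by 1.57 ± 0.24 and Nfkbia, the inhibitor IkB-alpha, by 1.58 ± 0.29. Of the 41 measured targets 6 rose, 0 fell and 35 did not pass (9 rose adjusted over the list alone). Their mean was 0.47 (camera adjusted p = 4.12e-12, adjusted p = 0.051 with an estimated correlation). Acod1, which makes itaconate in activated macrophages, rose at least 12.3-fold, the inhibitory receptor gene Pilra 12.3-fold (3.62 ± 0.48) and Clec7a, a receptor for fungal glucans, at least 3.11-fold. Among 15 monocyte and macrophage markers 3 rose, Ly6c1, Lyz1 and Tlr2 (5 adjusted over the list alone; camera adjusted p = 1.17e-05, adjusted p = 0.129 with an estimated correlation).

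Mast cell and basophil markers were lower in D361E, 2 of 10 by the test over all genes and 4 adjusted over the list alone (mean -1.35; camera adjusted p = 5.16e-06, adjusted p = 0.051 with an estimated correlation). Fcer1a, the IgE-binding chain of the mast cell receptor, fell by 3.60 ± 0.66, and the protease gene Mcpt8 fell by 2.74 ± 0.56, with 3 and 1 of 4 D361E arrays above background. F13a1 fell by 7.20 ± 1.04, with the other probe of the gene at -4.44. Phlda1, on the list of BCR-ABL and STAT5 response genes, fell by 1.92 ± 0.31; 2 of the 29 measured members fell (3 adjusted over the list alone; adjusted p = 0.00314, adjusted p = 0.429 with an estimated correlation). In total 65 genes rose and 34 fell, and 68 passed with slide as a fixed block. With the sets of sample numbers as a fixed block 269 passed. Within the 3 slides that held both groups the mean change was 0.44, 0.31 and 0.49 for the NF-kB targets and -1.34, -1.30 and -1.55 for the mast cell markers. The total was 245 without the 3 arrays, all 99 included, 64 without D361E replicate 2 and 36 after normexp correction, which ended the call of 13 of the 23 named genes, Clec7a, Ly6c1, Lyz1, Tlr2 and Mcpt8 among them. Mcpt8 lost its call without VOID replicate 2 or D361E replicates 3 or 4, and Tlr2 with slide as a fixed block and without any 1 of VOID replicates 1, 2 and 3 and D361E replicates 2, 3 and 4.

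**Figure D3:**
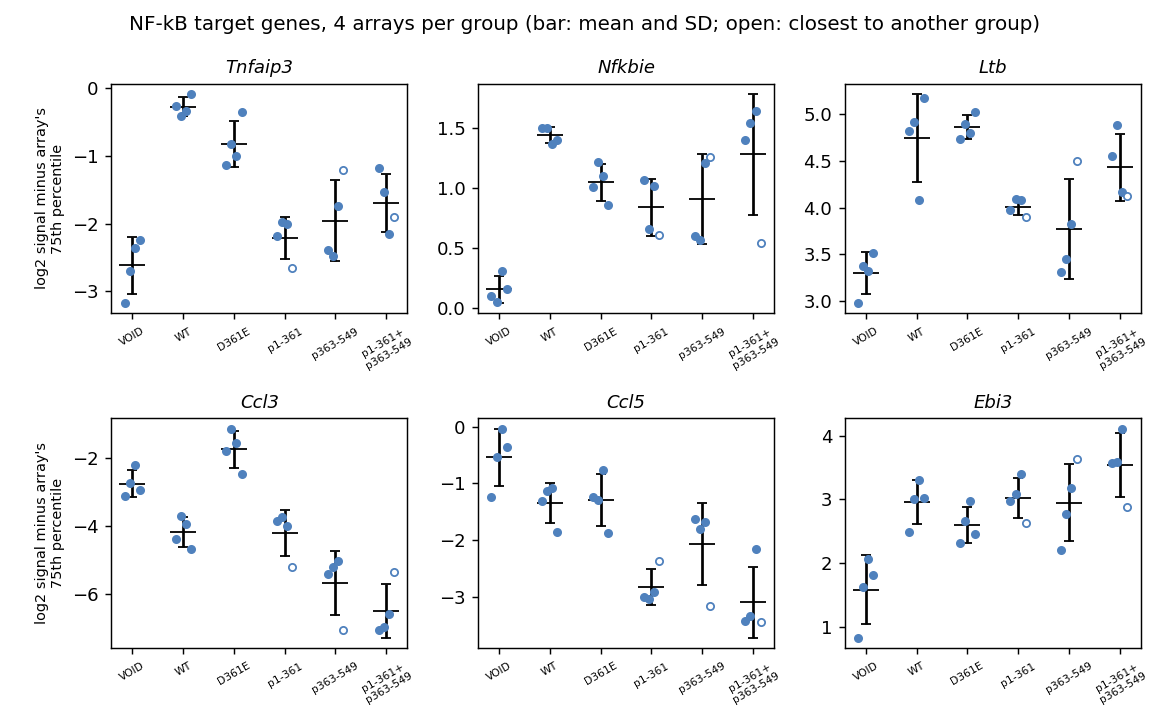
Log2 signal minus the array's 75th percentile for 6 NF-kB target genes (circles, 4 arrays per group; bars, mean and SD; open circles, the 3 arrays closest to another group). Tnfaip3, Nfkbie and Ltb were higher in WT and D361E than in VOID in all 4 arrays, and Ccl3 was lower with both fragments than in VOID in all 4.

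D361E against WT asked what the mutation changes, and few genes differed. Hif1a, the oxygen-regulated transcription factor, was higher in D361E by 1.14 ± 0.14 (log2, SE, n = 4 arrays per group; adjusted p = 0.000192), and the bicarbonate transporter gene Slc4a5 was higher by 3.35 ± 0.39, with 1 of 4 WT arrays above background. Grb7, an adaptor of receptor kinases, was lower by -1.51 ± 0.15, and Map3k19 was at least 2.77-fold lower. Hif1a was the 1 higher gene of 29 measured glycolysis and hypoxia genes, whose mean was -0.36 (2 higher adjusted over the list alone; camera adjusted p = 0.00234, adjusted p = 0.714 with an estimated correlation). NF-kB targets did not differ as a list (1 of 41 higher, Ccl3; adjusted p = 0.501; mean 0.03, median -0.02). In total 6 genes were higher and 6 lower, and 10 passed with slide as a fixed block. With the sets of sample numbers as a fixed block 34 passed, and 43 in a fit of these 8 arrays only. Within 2 slides the mean difference of the NF-kB targets was 0.05 and 0.09. The total was 82 without the 3 arrays, all 12 included, although these belong to other groups, 6 without WT replicate 1 or WT replicate 2, 7 without D361E replicate 1 or D361E replicate 2, and 5 after normexp correction, which ended the calls of Slc4a5, Map3k19 and Ccl3. Ccl3 also lost its call without any 1 of the 8 arrays except D361E replicate 4.

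The N-terminal fragment against VOID asked which genes this product of cleavage regulates. Podnl1 rose by 4.66 ± 0.59 (log2, SE, n = 4 arrays per group; adjusted p = 0.00015), and the carboxylesterase gene Ces2c rose by 3.34 ± 0.49, with 2 and 3 of 4 VOID arrays above background. Lyz1, a lysozyme gene, rose by 1.78 ± 0.25. Fcer1a fell by 5.36 ± 0.66, with 1 of 4 p1-361 arrays above background, and Cd200r2, of the CD200 receptor family, fell by 3.54 ± 0.25. C5ar1, the receptor of complement C5a, was at least 2.7-fold lower, and the chemokine gene Ccl5 fell by 2.28 ± 0.35. Podnl1 rose by 5.47 without the 3 arrays, and Fcer1a, then above background on 0 of 3 p1-361 arrays, was at least 23.8-fold lower.

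NF-kB targets had 1 of 41 higher, Ebi3, and 1 lower, Ccl5, in p1-361 (6 and 3 adjusted over the list alone; mean 0.13; camera adjusted p = 0.00957, adjusted p = 0.455 with an estimated correlation). Mast cell markers had 1 of 10 lower, Fcer1a (3 adjusted over the list alone; adjusted p = 0.000116, adjusted p = 0.0937 with an estimated correlation). Chemokines and cytokines had 1 of 20 lower, Ccl5 (4 adjusted over the list alone; adjusted p = 0.00245, adjusted p = 0.259 with an estimated correlation). The monocyte list had 2 of 15 higher, Lyz1 and Lyz2 (adjusted p = 0.00943, adjusted p = 0.386 with an estimated correlation), and missed the test without the 3 arrays (adjusted p = 0.109). In total 52 genes rose and 51 fell, and 71 passed with slide as a fixed block. With the sets of sample numbers as a fixed block 450 passed. Within 2 slides the mean change of the mast cell markers was -0.79 and, on the slide with p1-361 replicate 4, -1.02. With the 3 arrays left out 192 rose and 208 fell, 103 of the 400 shared. The total was 171 without p1-361 replicate 4, 67 without VOID replicate 1, 56 without VOID replicate 2, and 62, 52 and 54 without p1-361 replicates 1, 2 and 3. It was 25 after normexp correction, which ended 11 of 20 named calls, C5ar1, Ebi3 and Lyz2 among them, and 169 with array brightness as a covariate. Ebi3 lost its call without VOID replicates 1 or 2 or p1-361 replicates 1, 2 or 3.

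The C-terminal fragment against VOID asked the same of the other product. Cd200r2 fell by 4.31 ± 0.25 (log2, SE, n = 4 arrays per group; adjusted p = 8.61e-10). Itih3, a heavy chain of a plasma protease inhibitor, was at least 5.86-fold lower and C5ar1 at least 2.55-fold lower. Gpr183, a receptor for oxysterols, was at least 2.8-fold lower, and the chemokine gene Ccl3 at least 3.95-fold lower. F13a1 fell by 5.88 ± 1.04 and Fcer1a by 4.05 ± 0.66, each with 3 of 4 p363-549 arrays above background. The other F13a1 probe was at -4.14. Fam20a, a secretory pathway pseudokinase gene, rose by 2.59 ± 0.36, with 3 of 4 VOID arrays above background. These changes were, without the 3 arrays, -4.03 for Cd200r2, -4.43 for F13a1, -3.18 for Fcer1a and 2.95 for Fam20a, and all 4 still passed.

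Mast cell markers were lower in p363-549, 1 of 10 by the test over all genes, Fcer1a, and 5 adjusted over the list alone (mean -1.51; camera adjusted p = 3.43e-08, adjusted p = 0.0499 with an estimated correlation). Part of this mean came from replicate 4, 1 of the 3 arrays: within 3 slides it was -1.39, -0.68 and, on the slide with that array, -3.02. Without the 3 arrays the mean was -1.06 (adjusted p = 4.38e-08, adjusted p = 0.0118 with an estimated correlation). Chemokines and cytokines had 2 of 20 lower, Ccl3 and Ccl5 (3 adjusted over the list alone; adjusted p = 5.31e-06, adjusted p = 0.0937 with an estimated correlation). NF-kB targets had 2 of 41 higher, Tnip1 and Ebi3, and 2 lower, Ccl3 and Ccl5 (6 and 2 adjusted over the list alone; mean 0.11; adjusted p = 0.0155, adjusted p = 0.5 with an estimated correlation); without the 3 arrays the list missed the test (adjusted p = 0.72). Tnip1, Ebi3 and Ccl5 were also among the 6 of 18 named genes that lost their call without the 3 arrays, with Ces2c, St8sia4 and Itgb7. In total 26 genes rose and 60 fell, and 63 passed with slide as a fixed block. With the sets of sample numbers as a fixed block 137 rose and 134 fell, so the larger share of falls depends on the fit. Without the 3 arrays 44 rose and 87 fell, 72 of the 131 shared. The total was 46 without VOID replicate 2, 57 without p363-549 replicate 3, 49 without VOID replicate 4, 21 in a fit of these 8 arrays only, which ended the calls of F13a1 and Fcer1a, and 12 after normexp correction, which ended 15 of 18 named calls and left Cd200r2, F13a1 and Fcer1a. Of the named genes 9 kept their call whichever 1 array was left out; Tnip1, Ebi3 and Ccl5 lost it without VOID replicate 2 or p363-549 replicate 4.

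Both fragments together against VOID asked what the products of cleavage do jointly, and 669 genes passed, where no other construct gave more than 103 against VOID. Among mast cell genes, Fcer1a was at least 30.7-fold lower, the protease genes Cpa3 and Cma1 fell by 6.49 ± 1.03 and fell by 5.08 ± 0.98 (log2, SE, n = 4 arrays per group, adjusted p = 7e-04 and 0.00373), and Mcpt8 fell by 2.71 ± 0.56. Cpa3 was above background on 2 and Mcpt8 on 1 of the 4 both-fragment arrays. Of 10 measured mast cell markers 0 rose, 4 fell and 6 did not pass; adjusted over the list alone, 7 fell (mean -2.54; camera adjusted p = 2.87e-07, adjusted p = 0.0499 with an estimated correlation). Tph1, the enzyme of serotonin synthesis, fell by 5.67 ± 1.09, with 2 of 4 both-fragment arrays above background. Il2ra, a chain of the interleukin 2 receptor, fell by 7.24 ± 1.12, and F13a1 fell by 8.67 ± 1.04, with 3 and 1 of those arrays above background. The platelet chemokine gene Pf4 rose by 3.51 ± 0.62. Without the 3 arrays the changes were -7.61 for Cpa3, -6.22 for Cma1, -6.74 for Tph1 and -8.60 for Il2ra, with 1 (Cpa3), 1 (Tph1) and 2 (Il2ra) of the 3 both-fragment arrays above background. F13a1 was then above background on 0 of 3 and at least 416-fold lower. With all arrays, the other F13a1 probe was lower too, at a log2 change of -4.53.

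Signalling genes downstream of Bcr-Abl and STAT5 were lower with both fragments: of 29 measured, 0 rose, 7 fell and 22 did not pass (1 rose and 11 fell adjusted over the list alone; adjusted p = 5.67e-05, adjusted p = 0.256 with an estimated correlation). Socs1, a feedback inhibitor of cytokine signalling, fell by 2.37 ± 0.35, and the cytokine gene Osm fell by 2.72 ± 0.48. Chemokines and cytokines had 2 of 20 higher and 9 lower (the same numbers adjusted over the list alone; adjusted p = 2.1e-05, adjusted p = 0.129 with an estimated correlation): Ccl3 was at least 5.2-fold lower, and Ccl5 fell by 2.55 ± 0.35. NF-kB targets went both ways, 11 of 41 higher and 3 lower (15 and 4 adjusted over the list alone; mean 0.27; adjusted p = 8.7e-05, adjusted p = 0.246 with an estimated correlation). Ebi3, a cytokine subunit, rose by 1.95 ± 0.30 and Tnip1, a partner of the Tnfaip3 protein, by 0.88 ± 0.15. Casp4, an inflammatory caspase, rose by 1.24 ± 0.16.

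Interferon-stimulated genes had 5 of 33 higher and 1 lower with both fragments (12 and 1 adjusted over the list alone; adjusted p = 0.000387, adjusted p = 0.246 with an estimated correlation). Gbp4 fell by 3.54 ± 0.64, with 1 of 4 both-fragment arrays above background, and Eif2ak2, the double-stranded RNA kinase, rose by 0.85 ± 0.20 (log2, SE). G2 and mitosis genes had 3 of 39 higher, Ndc80, Ect2 and Cdc25c (4 adjusted over the list alone; mean 0.44; adjusted p = 2.49e-11, adjusted p = 0.3 with an estimated correlation). The other Ect2 probe differed in sign, at -0.42 (adjusted p = 0.7) against 0.67 for the probe used. Adhesion and migration genes had 4 of 19 lower, Itgb7, Selplg, Cxcr4 and Ccr7 (4 adjusted over the list alone; adjusted p = 0.0137, adjusted p = 0.229 with an estimated correlation); Itgb7, an integrin chain, fell by 1.16 ± 0.18. Csf2rb, the chain shared by the receptors of interleukin 3 and GM-CSF, fell by 1.14 ± 0.21, 1 of 3 lower genes among 13 measured myeloid genes (4 adjusted over the list alone; adjusted p = 0.0024, adjusted p = 0.333 with an estimated correlation). T and NK markers had 3 of 10 lower, Lat, Cd3d and Gzmb, and missed the test as a list (2 higher and 3 lower adjusted over the list alone; adjusted p = 0.0831).

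With both fragments 292 genes rose and 377 fell, and with the sets of sample numbers as a fixed block 1336 rose and 1089 fell. Within 2 slides the mean change of the mast cell markers was -2.69 and -3.29. Leaving out the 3 arrays, 690 rose and 750 fell, 655 of the 1440 shared. The total was 1056 without both fragments replicate 4, 324 and 303 without both fragments replicates 1 and 2, and 437, 433 and 441 without VOID replicates 2, 3 and 4. It was 212 after normexp correction, which ended 23 of 51 named calls, Gbp4, Eif2ak2, Mcpt8, Ccl3, Cxcr4, Ccr7, Ndc80, Ect2 and Cdc25c among them, 294 in a fit of these 8 arrays only, 410 with slide as a fixed block, 437 with no filter on dim probes and 321 with array brightness as a covariate. Of the named genes 37 kept their call whichever 1 array was left out. Eif2ak2, Ect2, Cdc25c, Cd3d, Gzmb and Ccr7 did not: each lost it without both fragments replicate 2, and all but Ect2 without replicate 1.

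**Figure D4:**
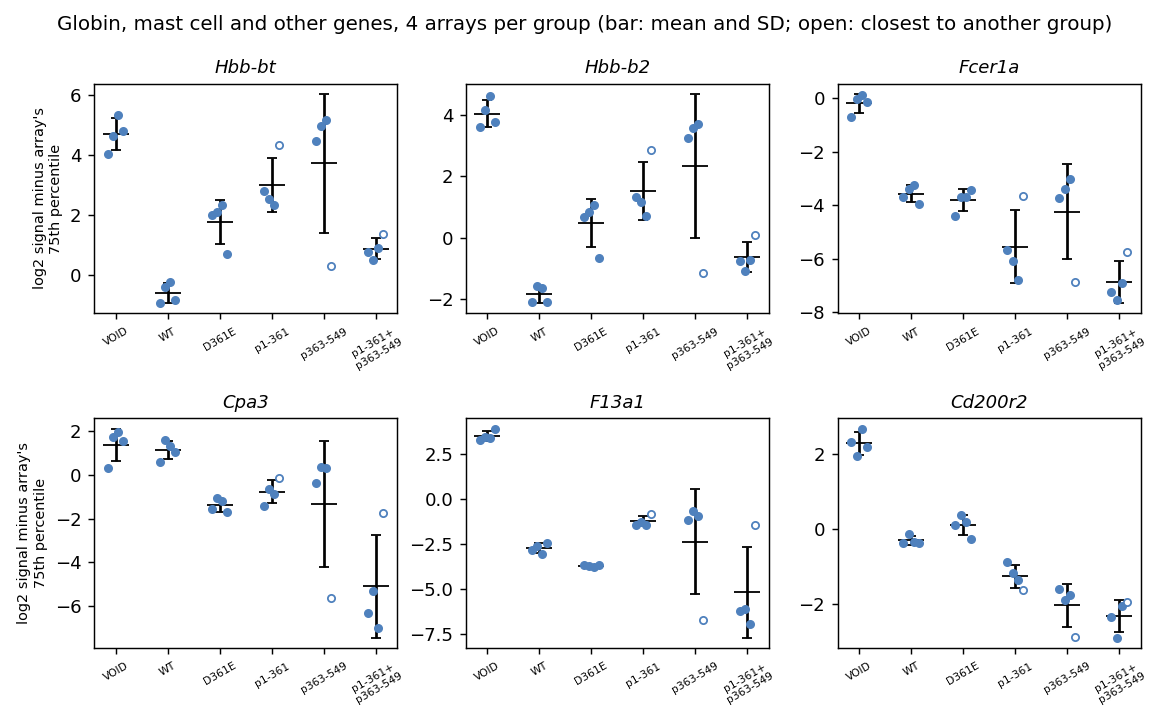
Log2 signal minus the array's 75th percentile for globin genes (Hbb-bt, Hbb-b2), mast cell genes (Fcer1a, Cpa3), F13a1 and Cd200r2 (circles, 4 arrays per group; bars, mean and SD; open circles, the 3 arrays closest to another group). Hbb-bt was 0.29 in p363-549 replicate 4, against a mean of 4.87 in the other 3 arrays of that group.

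Each fragment against WT asked how a product of cleavage differs from the intact protein. Tnfaip3 was lower than in WT by -1.93 ± 0.27 in p1-361 (log2, SE, n = 4 arrays per group; adjusted p = 0.00119) and by -1.68 ± 0.27 in p363-549 (adjusted p = 0.0062). NF-kB targets were lower as a list in both: 1 of 41 in p1-361, and 8 adjusted over the list alone (mean -0.32; camera adjusted p = 1.2e-08, adjusted p = 0.0937 with an estimated correlation), and 1 of 41 in p363-549, and 7 adjusted over the list alone (mean -0.33; adjusted p = 1.22e-08, adjusted p = 0.0937 with an estimated correlation). Itih3 was lower by -4.33 ± 0.45 in p1-361, with 3 of 4 arrays above background, and at least 21.6-fold lower in p363-549. Il13, a cytokine of type 2 immunity, was at least 8.03-fold lower in p363-549, where chemokines and cytokines had 1 of 20 lower (4 adjusted over the list alone; adjusted p = 8.45e-08, adjusted p = 0.051 with an estimated correlation). Map3k19 was at least 2.16-fold and at least 2.05-fold lower in p1-361 and p363-549. The globin gene Hbb-bt was higher in p363-549 by 4.32 ± 0.72, and without the 3 arrays by 5.47.

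For p1-361 against WT, 7 genes were higher and 12 lower, and 15 passed with slide as a fixed block. For p363-549 against WT, 5 were higher and 17 lower, and 18 passed with that block. Within 3 slides each the mean difference of the NF-kB targets was -0.26, -0.25 and, on the slide with replicate 4, -0.51 in p1-361 and -0.54, -0.35 and -0.50 in p363-549. The totals without the 3 arrays were 105, all 19 included, and 101, 21 of the 22 included. The p1-361 total was 11 and 9 without WT replicates 1 and 2, 9 and 10 without p1-361 replicates 2 and 3, and 7 after normexp correction. The p363-549 total was 43 without p363-549 replicate 4, 14, 12 and 13 without replicates 1, 2 and 3 of that group, 13 without WT replicate 2 or WT replicate 4, 9 after normexp correction, 7 in a fit of these 8 arrays only and 8 with brightness as a covariate. Normexp correction ended the calls of Map3k19 and Il13, and the fit of 8 arrays and the brightness covariate each ended those of Tnfaip3 and Hbb-bt in p363-549. Hbb-bt also lost its call without p363-549 replicates 2 or 3.

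Both fragments against WT asked whether the products together act like the intact protein. Cpa3 was lower by -6.25 ± 1.03 (log2, SE, n = 4 arrays per group; adjusted p = 0.00412), and Itih3 by -5.30 ± 0.45, with 2 and 1 of 4 both-fragment arrays above background. Leaving out the 3 arrays, Cpa3 was lower by -7.37, with 1 of 3 above background. Il13 was at least 10.6-fold lower, and the chemokine gene Ccl17 was lower by -1.53 ± 0.21. Tnfaip3 was lower by -1.41 ± 0.27 and Itgb7 by -1.15 ± 0.18. B3gnt5, a glycosyltransferase gene, was higher by 3.03 ± 0.37, with 2 of 4 WT arrays above background. Mast cell markers had 3 of 10 lower, Cpa3, Fcer1a and Cma1 (7 adjusted over the list alone; mean -1.94; camera adjusted p = 1.07e-06, adjusted p = 0.0499 with an estimated correlation). Chemokines and cytokines had 7 of 20 lower (1 higher and 9 lower adjusted over the list alone; adjusted p = 1.15e-07, adjusted p = 0.051 with an estimated correlation). BCR-ABL and STAT5 response genes had 4 of 29 lower, Osm, Il2ra, Ier3 and Socs1 (10 adjusted over the list alone; adjusted p = 4.81e-07, adjusted p = 0.149 with an estimated correlation). NF-kB targets had 4 of 41 lower, Ccl3, Tnfaip3, Ccl5 and Ier3, and did not differ as a list (adjusted p = 0.319), with a mean of -0.17 and a median of 0.09.

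Against WT, 16 genes were higher and 143 lower with both fragments, but with the sets of sample numbers as a fixed block 573 were higher and 537 lower, so the larger share of lower genes depends on the fit. Within 2 slides the mean difference of the mast cell markers was -2.21 and, on the slide with replicate 4 of both fragments, -0.92. Without the 3 arrays 309 were higher and 526 lower, all 159 included. The total was 494 without both fragments replicate 4, 33 and 34 without both fragments replicates 1 and 2, and 66, 37, 64 and 62 without WT replicates 1 to 4. It was 24 after normexp correction, which ended 17 of 24 named calls, 84 with probes above background on all 24 arrays, 52 in a fit of these 8 arrays only, which ended 16, 31 with slide as a fixed block, 62 with no filter on dim probes and 76 with brightness as a covariate. Of the named genes 7 kept their call whichever 1 array was left out, Cpa3, Itih3, Il13, Ccl17, Tnfaip3, Itgb7 and B3gnt5, but normexp correction ended those of Il13, Ccl17 and B3gnt5, and the fit of 8 arrays that of Itgb7. Fcer1a, Cma1, Osm, Il2ra, Ier3, Socs1, Ccl3 and Ccl5 did not; each lost it without any 1 of both fragments replicate 1, both fragments replicate 2 and WT replicate 2, and with slide as a fixed block.

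The additivity test asked whether both fragments together changed a gene by the sum of their separate changes against VOID. Positive values mean that the joint change lay above the sum. Cd200r2 was above the sum by 3.25 ± 0.35 (log2, SE, n = 4 arrays per group; adjusted p = 0.000102): against VOID it fell by 3.54 in p1-361, by 4.31 in p363-549 and by 4.59 with both. Lyz1 was below the sum by -2.32 ± 0.35, and Igsf5, of the immunoglobulin superfamily, by -2.49 ± 0.40, or -3.12 without the 3 arrays. A signal cannot fall below background, so the sum of 2 falls can lie lower than any measurable joint change. Itih3 was above the sum by 3.37, and without the 3 arrays it was above background on 0 of 3 both-fragment arrays. Tfpi (4.25) and Asap2 (3.68) were then above background on 0 of 3 p1-361 arrays. In total 18 genes were above and 14 below, the arrays of 4 groups entering each value. How many of the 18 owe their place to this limit was not tested. With the sets of sample numbers as a fixed block 830 passed. Without the 3 arrays, which enter every value here, 609 were above and 983 below, with all 32 included. The total was 57, 361 and 194 without replicate 4 of p1-361, p363-549 and both fragments in turn. It was 3 after normexp correction, which ended the calls of Lyz1 and Igsf5, 13 with probes above background on all 24 arrays, 20 in a fit of the 16 arrays only, 21 with no filter on dim probes and 13 with brightness as a covariate, which ended the call of Igsf5. Among the lists, the 15 measured heat shock genes, of which 0 passed, had a mean of 0.46 (camera adjusted p = 0.00494, adjusted p = 0.436 with an estimated correlation).

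Across the 5 constructs, 23 genes differed from VOID in the same direction in all 5, 6 higher and 17 lower. The higher genes included Casp4, the carboxylesterase genes Ces2b and Ces2c, and Podnl1, with Casp4 up by 1.03 to 1.35 (log2). The lower genes included Cd200r2, Fcer1a, F13a1, Vwf, the complement receptors C5ar1 and C5ar2, the interleukin 4 receptor gene Il4ra and the embryonic globin gene Hbb-y. C5ar2 here, and Hba-a2 among the globins, were singled out after their values were seen. The number without the 3 arrays was 40, with 22 of the 23 included. The 2 single fragments shared 55 genes in the same direction and 0 in opposite directions, and 104 and 1 without the 3 arrays. Independent lists would share 0.29. In 50 simulations of unchanged groups against shared VOID arrays at most 0 called genes were shared. That number says little, because unchanged groups give few calls. Equally long lists of the top genes in these simulations shared a mean of 11, at most 17. With the VOID arrays split between the 2 fragments, which leaves 2 each, 14 to 19 genes were shared and 0 were opposite over 6 splits. The log2 changes of 2 constructs against the shared VOID arrays correlated across genes with an r of 0.341 (D361E and both fragments) to 0.781 (p1-361 and p363-549). A shared control alone gave 0.5 in simulations, with a highest value of 0.519. The covariance ran from 0.0577 to 0.1133, against 0.0436 simulated. With the VOID arrays split between the constructs, 2 to each, the r ran from 0.101 to 0.332. All these values keep the 3 arrays, so each fragment group holds 1 array that resembled another fragment group. The highest pair includes p1-361 replicate 4, which had an r of 0.78 with the p363-549 mean. The correlations of changes are not given without the 3 arrays. Genes are not independent replicates in these correlations.

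Of the 320 list tests, 97 passed with the preset correlation. With an estimated correlation 4 held: NF-kB targets in WT against VOID, and mast cell markers in p363-549 against VOID, both fragments against VOID and both fragments against WT. Random regroupings of the arrays gave a median of 67 list calls (28 to 103). With the 3 arrays left out 85 lists passed, 75 of the 97 among them. In simulated data with 50 changed genes at each size, limma found 60% of 2-fold and 94% of 4-fold changes in WT against VOID, and 26% and 82% in the additivity test. All 4 arrays of a changed group changed alike there. The additivity shares so do not cover fragment groups that hold an array resembling another group.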

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

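The tests of the resemblance of arrays to groups, the globin tests, the regroupings within the sets of sample numbers and the alternative without 3 arrays were chosen after the result was seen. The other tests here were chosen before.

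The joint change of both fragments differed from the sum of the separate changes for 32 genes, a difference between groups that was tested as an interaction. Of 263 groups of 4 values checked, 22 held 1 array far from the other 3, where chance gives 13.2. Values below are log2 levels, with the mean of the other 3 arrays. The share of spots well above background was 49.4% in WT replicate 4 (51.93% in the others), and the negative control mean was 35.7 in both fragments replicate 4 (32.67). In p1-361 replicate 4, Podnl1 was -2.34 (0.92), Nupr1 -0.39 (-3.28) and Ccl5 -2.36 (-2.98). In p363-549 replicate 4, Hbb-bt was 0.29 (4.87), Hbb-b2 -1.16 (3.51) and Ccl5 -3.15 (-1.71). In both fragments replicate 4, Slc17a8 was -4.43 (-0.35), Lyz1 -1.52 (-2.61), Casp4 3.07 (3.52), Idi1 1.99 (4.22), Tlr2 -1.42 (-1.05), Cma1 1.82 (-2.75), Cd3d 1.55 (0.36) and Gzmb 5.23 (-2.75). In both fragments replicate 3, B3galt5 was -3.75 (-2.03), Ccl5 -2.16 (-3.40) and Lat 2.42 (2.02). Cdc25c was -0.55 (-0.96) in both fragments replicate 2, Arl6ip1 was -1.66 (-0.84) in WT replicate 3, and Idi1 was 2.85 (1.94) in VOID replicate 3.

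The 3 fragment arrays numbered 4 resembled another fragment group more than their own: p1-361 resembled p363-549, p363-549 resembled both fragments, and both fragments resembled p1-361. Of all 24 arrays only these 3 were out of place, and the groups they resembled form a closed cycle of the same 3 arrays, so labels exchanged among these arrays are a candidate explanation. Tests argue against a disturbance of the whole set of arrays with the same title-number set, since 0 of the other 3 arrays of that set were out of place, and against RNA of 2 groups mixed in equal parts, since the arrays lay at least 0.9 of the way from their own group mean to the other. The exchange, if there was one, may lie in the samples, the hybridization or the deposit, and cells that received another plasmid than labelled would look the same; no test here separates these. The association of file, title and group was checked and no error was found there, and a biological difference of these 3 samples was not tested.

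In all 5 constructs, 23 genes differed from VOID in the same direction. Simulated unchanged groups against a shared VOID gave at most 0 such genes. Unchanged groups with independent values leave few genes past the threshold, so this simulation could hardly give more and does not decide. Any other group taken as the common reference gave at most 2, so a mere common reference does not account for the number. WT and D361E, which hold none of the 3 fragment arrays numbered 4, gave 2 and 1 as the reference. Among the 5 constructs themselves 3 of the 23 genes differed. An effect that every p65 construct shares and a difference of the empty-plasmid cells that p65 does not cause cannot be told apart, because VOID is the only control group and carries no p65.

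All 7 globin genes were lower in WT than in VOID. No single VOID or WT array accounts for it: with any 1 array left out, every called globin gene stayed at -2.184 or lower. Lower globin signal was not confined to WT. Hbb-bs was also lower than in VOID in D361E (-4.47), p1-361 (-3.88) and with both fragments (-6.37). The limma adjusted p was 0.0136, 0.0444 and 0.000212. In p363-549 replicates 1 to 3, Hbb-bt was 4.47, 4.97 and 5.16, within the VOID range of 4.04 to 5.32. Erythroid cells in the VOID samples would bring their other transcripts. The median change of 7 other erythroid markers was -0.228, but most of these are abundant in the line itself, so this value does not decide, as was judged after it was seen. Erythroid cells in the VOID samples so stay open, and a globin change within the leukaemia cells was not tested.

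Other splits of the arrays asked how often another grouping gave as many calls. Of the 35 splits of 8 arrays, 1 split, the real one, gave as many genes in WT against VOID (73, highest other 0), D361E against VOID (99, 0), p1-361 against VOID (103, 5), p363-549 against VOID (86, 2), both fragments against VOID (669, 80), D361E against WT (12, 1), p1-361 against WT (19, 0) and both fragments against WT (159, 23). That share is under the 0.05 set beforehand and is the smallest that 35 splits can give. It was not adjusted for the number of comparisons, so it does not exclude chance for each of them. For p363-549 against WT 2 of the 35 splits gave as many (22, highest other 23), and for additivity 5 of 100 regroupings (32, highest other 4718), so chance cannot be excluded. Why some regroupings gave more calls was not tested. With the sets of sample numbers as a block and labels exchanged only within them, 4 of 100 regroupings gave as many for additivity (830, highest other 2147). That share is under 0.05, but the test was chosen after the regroupings without sets had given 5 of 100, so it does not exclude chance. The 8 exchanges within the sets for p363-549 against WT, of which 1, the real one, gave as many (43, highest other 1), are too few for a share under 0.05. The F test count (424, highest other 940) and the count of list calls (97, highest other 103) were reached by 2 and 3 of 100 regroupings, the real grouping included. Both shares are under 0.05, but random regroupings gave a median of 67 list calls. The count of 97 so does not show that a given list call is beyond chance.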

How the results depend on the processing

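The settings with the sets of sample numbers, array brightness, detected probes and the 3 arrays left out were chosen after the result was seen. Counts are in the order WT, D361E, p1-361, p363-549 and both fragments against VOID, then D361E, p1-361, p363-549 and both fragments against WT, then additivity, then the F test; a comparison is named where others stayed within 1.5 times. Over all settings, named genes kept their side of the threshold in 4456 cases, lost the call in 753 and gained one in 12. None that was called in either fit reversed its direction. Direction was not checked for genes called in neither fit, so uncalled values of Rela, Abl1 and Bcr count as kept whatever their sign. Abl1 in p1-361 against VOID, for example, went from -0.05 to 0.06 without the 3 arrays. List calls held in 450 cases and were lost in 326. Counts stayed within 1.5 times in 175 cases and moved in 121. The authors' series table holds the same values, so its 218 named results in this tally could not differ. The tally also counts 213 unchanged results under array weights, which are doubted below. Normexp correction gave 27, 36, 25, 12, 212, 5, 7, 9, 24, 3 and 136. Probes well above background on all 24 arrays, which tests fewer genes, gave 32, 52, 44, 28, 4 (D361E against WT), 6, 7, 84, 13 and 257. Fits of only the arrays compared, with fewer samples, gave 116 (WT), 21 (p363-549), 294 (both), then 43, 31, 7 and 52 against WT and 20 for additivity. Slide as a fixed block gave 410 (both) and 31 (both against WT). No filter on dim probes gave 437 (both), 62 (both against WT) and 21 (additivity). Brightness gave 169 (p1-361), 321 (both), 8 (p363-549 against WT), 76 (both against WT) and 13 (additivity). Sets as a block gave 221, 269, 450, 271, 2425, 34 (D361E against WT), 43 (p363-549 against WT), 1110, 830 and 1671. For both fragments against VOID, the only comparison so checked, 20 permuted labelings under this block gave 0 calls. Array weights gave 1633, 1888, 701, 494, 5357, 2751, 378, 1491, 8072, 5997 and 11165, but the weights ran from 0.247 to 8.803, and their estimate did not converge. With these weights 5 of 20 permuted labelings gave calls for both fragments against VOID, up to 3080, and no other comparison was so checked. Without the 3 arrays the counts were 191, 245, 400, 131, 1440, 82, 105, 101, 835, 1592 and 1480. Each array left out in turn gave 45 to 59, 64 to 103, 52 to 171, 46 to 76, 303 to 1056, 6 to 11, 9 to 27, 12 to 43, 33 to 494, 24 to 361 and 252 to 795. List calls fell to 4 with an estimated correlation, to 12 with it and without the 3 arrays, and to 25 with fry. The mean r between constructs was 0.586 and 0.233 with VOID split, which removes the shared control and also leaves 2 VOID arrays per change. For the other moved counts the cause was not tested. No filter moved the median of all genes in both fragments against VOID from -0.007 to -0.20. Signal over background limits the folds of genes dim in 1 group.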

Other observations

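The tests of the sets of sample numbers were chosen after the result was seen.

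Some gene groups not described above passed the list test although few or none of their members passed, and none held with an estimated correlation. In D361E against WT the test pointed down for stress response genes of the unfolded protein pathway (0 of 28 passed; mean -0.21; camera adjusted p = 1.22e-05, adjusted p = 0.181 with an estimated correlation) and G2 and mitosis genes (0 of 39; mean -0.16; adjusted p = 5.4e-06, adjusted p = 0.508 with an estimated correlation). It pointed up for p53 targets (0 of 21; mean 0.21; adjusted p = 0.000911, adjusted p = 0.386 with an estimated correlation) and neutrophil markers (0 of 7, and 2 adjusted over the list alone; mean 0.92; adjusted p = 0.0145, adjusted p = 0.129 with an estimated correlation). For both fragments against WT it pointed up for S phase and replication genes (0 of 37; mean 0.46; adjusted p = 2.65e-05, adjusted p = 0.678 with an estimated correlation), oxidative phosphorylation genes (0 of 43; mean 0.18; adjusted p = 0.00182, adjusted p = 0.638 with an estimated correlation) and DNA repair genes (0 of 33; mean 0.24; adjusted p = 0.0169, adjusted p = 0.638 with an estimated correlation), the last of which missed the test without the 3 arrays (adjusted p = 0.156). For both fragments against VOID, cholesterol synthesis genes had 1 of 24 higher (mean 0.32; adjusted p = 0.0357, adjusted p = 0.802 with an estimated correlation), MHC class II genes 1 of 7 lower, and 4 adjusted over the list alone (mean -0.79; adjusted p = 0.00522, adjusted p = 0.129 with an estimated correlation), and immediate early genes 1 of 20 lower, and 3 adjusted over the list alone (mean -0.53; adjusted p = 0.00143, adjusted p = 0.24 with an estimated correlation). In p1-361 against VOID, 0 of 22 MHC class I genes passed, and 3 were higher adjusted over the list alone (mean 0.25; adjusted p = 0.000136, adjusted p = 0.192 with an estimated correlation). In p363-549 against WT the test pointed down for autophagy and lysosome genes (0 of 28; mean -0.11; adjusted p = 0.000506, adjusted p = 0.386 with an estimated correlation) and checkpoint and costimulation genes (0 of 16, and 1 adjusted over the list alone; mean -0.17; adjusted p = 0.0152, adjusted p = 0.235 with an estimated correlation).

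Among the lists on cell death, pro-apoptotic genes had 1 of 27 higher in each construct against VOID, Casp4 with both fragments (mean 0.18; camera adjusted p = 0.0409, adjusted p = 0.386 with an estimated correlation), and the list missed the test there without the 3 arrays (adjusted p = 0.0812). Anti-apoptotic genes passed in no comparison; the value for WT against VOID was 0.264. The same held for NF-kB pathway components (0.264), antioxidant genes (0.948), ribosome biogenesis and MYC targets (0.151), B lymphocyte markers (0.501) and fibroblast and epithelial markers (0.522), each an adjusted p for WT against VOID.

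Arrays of the same set of consecutive sample numbers deviated together from their group means. Residuals across genes correlated with a mean r of 0.346 within a set and -0.116 between sets, and 17 of the 24 arrays were closest to an array of their own set. On the same slide the mean r was 0.017. Genes are not independent replicates in these correlations, and the labels do not say what the sets are.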
